A study of Homo sapiens with 6 samples.

How the data were processed

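RNA from 6 samples labelled K562, all kept under hypoxia, was measured on Affymetrix expression arrays with 1 array per sample. K562 is an established line derived from a chronic myeloid leukaemia in blast crisis. Per the labels, 3 samples had received siRNA against NFIL3 and 3 a control siRNA, and the groups are called siNFIL3 and siControl here. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. The sources used here give no scan date or batch, so no batch could be set against the groups.

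The deposited values were on the log2 scale, and the submitters' processing notes name RMA and Affymetrix Expression Console 1.3.1. RMA corrects background, quantile-normalizes probes and summarises them per transcript cluster. Its settings and the genome build were not given in the sources used here, so no coordinates are printed. The table held 65528 rows with values from 1.78 to 19.93 and a median of 3.72. Array medians ran from 3.67 to 3.77, so the deposited columns were close to a common scale and were used without further normalization. No detection calls were used, and levels near the table median cannot be told from background. In 31 rows every array lay within 0.05 of its own maximum, where differences are compressed, and 3 of these rows had a gene symbol of their own.

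Rows were named through the platform annotation. It gave exactly 1 gene symbol to 22755 rows, several to 1389 and none here to 41384. Entrez identifiers matched 20539 of the rows to the RefSeq gene table of assembly GRCh38.p14, which was used only for names, biotypes and neighbouring genes and updated 0 symbols. Rows with 1 symbol were tested, with 1 row per gene, the row with the highest mean over the 6 arrays. This left 22445 genes, of which 17072 were protein-coding, and 296 genes had more than 1 row. In 5 of those 296 genes, rows past the threshold went in opposite directions. Values equal to those of another row were found for 58 named rows.

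Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, siNFIL3 minus siControl, 2-sided), and p was adjusted by the Benjamini-Hochberg method over the 22445 genes with a threshold of 0.05. Rose, fell and changed refer to this threshold. Gene lists were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the lists, with the correlation estimated from the data and fry as alternatives. The 28 lists were written from textbook knowledge, and 27 had measured members. Mitochondrial-encoded genes had 0 measured members, so that list is void. Some genes belong to several lists.

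The design, the limma and list tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined. Exceptions are the tests and the alternative named as later choices, and tests of explanations for patterns seen in the data. The rule named NFIL3, then in each direction the 12 genes with the largest log2 fold among those past the threshold. Each of these had groups that did not overlap and a higher group mean above the table median. Symbols of uncharacterised loci, small RNAs, olfactory receptors, antisense transcripts and pseudogenes were passed over there. In each list, up to 2 members that rose most and 2 that fell most could be named, or where none passed the 2 with the smallest unadjusted p.

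The scripts were tested on simulated data for siNFIL3 against siControl with 22445 genes, of which 200 were changed. limma called 58% of 1.5-fold and 90% of 2-fold changes, and 5.1% of calls were unchanged genes. With the fitted log2 folds of the 5171 genes called in the real comparison laid on simulated arrays, 83.4% were called. Those folds came from genes already called, which can raise this share. A list with a built-in shift was called and 0 lists without a shared member were called by camera. The simulated genes were independent of each other, so false calls of lists with correlated members were not tested. The alternatives were quantile normalization, centring of arrays, a filter on dim genes, a trended robust prior, array weights, the replicate number as a block, the mean of a gene's rows, all rows of the table, other thresholds, an unmoderated model, and each array left out in turn. Random lists matched on mean expression were drawn 10000 times from 50 level bins. Bootstrap intervals (95%) used 10000 draws.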

Results

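The data compare NFIL3 depletion with a control siRNA under hypoxia, with 3 arrays in each group. NFIL3 is a basic leucine zipper transcription factor that represses D-box promoters. All 6 arrays were from hypoxic cells, so every difference is between siRNAs within hypoxia. Across all rows, Pearson's correlation between arrays was 0.994 to 0.996 within siControl and 0.995 to 0.996 within siNFIL3. It was 0.981 to 0.989 over the 9 pairs of arrays from different groups. These are correlations across rows, which are not independent replicates.

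The arrays labelled K562 carried little signal for blood lineage genes in either group. The 35 measured erythroid genes had a median level of 3.57, at percentile 33.5 of all genes, and 20 of them lay below the table median. The 4 erythroid-list genes above the 75th percentile were TFRC, BLVRB, EPB41 and SLC25A37, which are also used outside the erythroid lineage. The erythroid transcription factor GATA1 was at 3.32 ± 0.01 in siNFIL3 and 3.24 ± 0.02 in siControl (SD, n = 3). The embryonic globin HBZ was at 2.92 ± 0.11 and 2.64 ± 0.08, and the leukocyte antigen PTPRC at 3.29 ± 0.01 and 3.25 ± 0.02. Median levels were 3.41 for megakaryocyte genes, 3.58 for granulocyte and monocyte markers and 3.54 for B, T and NK cell markers. The epithelial and fibroblast list had a median of 3.63, with 11 of its 20 genes below the table median and 5 (25%) above the 75th percentile, the share of genes at large. These were the mucin MUC1, the proteoglycans LUM and DCN, and the keratins KRT7 and KRT19. MUC1 was at 12.42 ± 0.09 in siNFIL3 and 11.88 ± 0.27 in siControl, and LUM at 11.12 ± 0.24 and 11.34 ± 0.13. Other members picked after their values were seen were low, with the epithelial adhesion genes EPCAM at 3.54 ± 0.02 and 3.50 ± 0.04 and CDH1 at 3.44 ± 0.01 and 3.38 ± 0.05. Among genes picked after their values were seen, EGFR, the epidermal growth factor receptor, was at 11.08 ± 0.22 and 11.69 ± 0.31. The housekeeping list had a median of 12.91. Levels of different rows are set side by side here only as positions in the table, since probes differ in brightness.

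**Figure D1:**
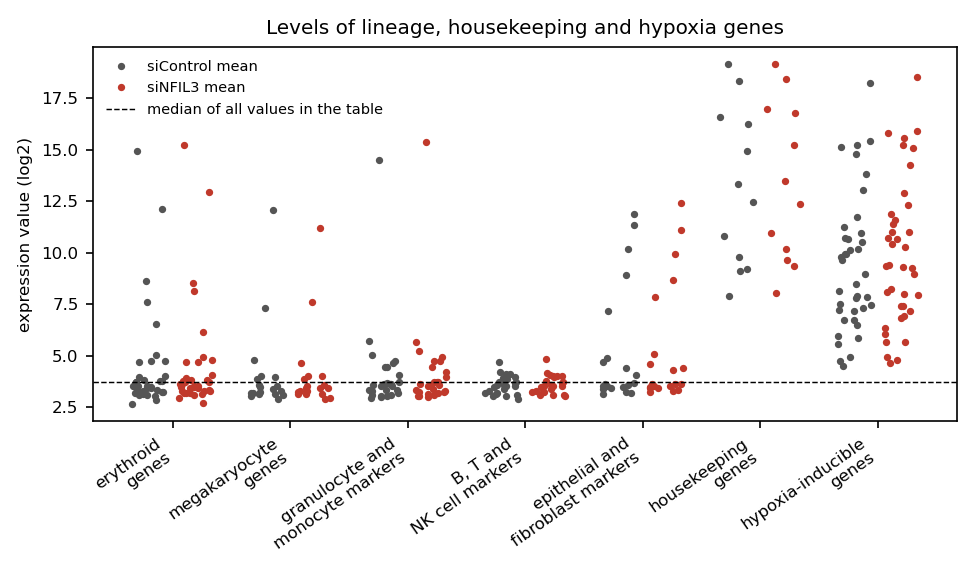
Mean log2 level in each group of arrays labelled K562 for members of the lineage, housekeeping and hypoxia-inducible lists. Each gene has a siControl point and a siNFIL3 point, each a mean of 3 arrays. Most erythroid genes sit near or below the table median of 3.72 while the housekeeping median is 12.91.

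NFIL3 itself, on its single row TC09001325.hg.1, was at 6.61, 6.42 and 6.33 in siNFIL3 replicates 1 to 3 and at 7.997, 8.22 and 7.88 in the siControl replicates. The means were 6.45 ± 0.14 and 8.03 ± 0.17 (SD, n = 3), a log2 fold of -1.58 (SE 0.11, 95% interval -1.84 to -1.32) or a 2.99-fold lower level, with a limma adjusted p of 0.00052. An exact permutation test gave p = 0.1, the smallest that 3 against 3 arrays allow.

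Genes of several kinds changed with the NFIL3 siRNA. PI3, which encodes the elastase inhibitor elafin, rose from 8.51 ± 0.39 to 11.67 ± 0.34 (log2 fold 3.16, SE 0.23), and GDF15, a stress-induced cytokine of the TGF-beta family, rose from 6.18 ± 0.32 to 8.93 ± 0.10 (2.75, SE 0.16). The orphan receptor gene GPR135 fell from 8.93 ± 0.27 to 5.24 ± 0.23 (-3.69, SE 0.17), and DKK1, a secreted Wnt antagonist, from 10.58 ± 0.13 to 7.04 ± 0.53 (-3.54, SE 0.24). Adjusted p was 0.000542 for PI3, 0.000356 for GDF15, 0.000343 for GPR135 and 0.000501 for DKK1. A second row of GPR135 had a log2 fold of -1.58, so the size of its decrease differed between rows.

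Next among the genes named upward by the rule, which passed over small RNAs, were the interferon-stimulated IFI6 (2.64) and IFI27 (2.36). The clock repressor PER1 (2.40), the stress transcription factor DDIT3 (2.32), the kinase PIM1 (2.26) and the metallothionein MT1X (2.07) were named too. HDAC3, a histone deacetylase, rose by 2.05, DEPDC7 by 1.96, the splicing-factor kinase CLK1 by 1.93 and LAMTOR5, a subunit of the lysosomal Ragulator complex, by 1.86. Next among the genes named downward were AGGF1 (-3.09), the chromatin silencing factor TASOR (-3.04) and ID1 (-3.01), an inhibitor of basic helix-loop-helix factors. The immediate early factor EGR1 (-2.91) came after these. LXN (-2.76), the p38 kinase activator MAP2K6 (-2.71), RBBP6 (-2.70), the sialic acid synthesis enzyme GNE (-2.70), the single-strand DNA binding NABP1 (-2.65) and the spindle gene ASPM (-2.62) followed. Standard errors of these 20 log2 folds lay between 0.12 and 0.50 and adjusted p between 0.000343 and 0.0135. IFI27 missed the threshold without siControl replicate 3 (log2 fold 2.17, adjusted p = 0.0564) or siNFIL3 replicate 1 (2.15, 0.0525).

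**Figure D2:**
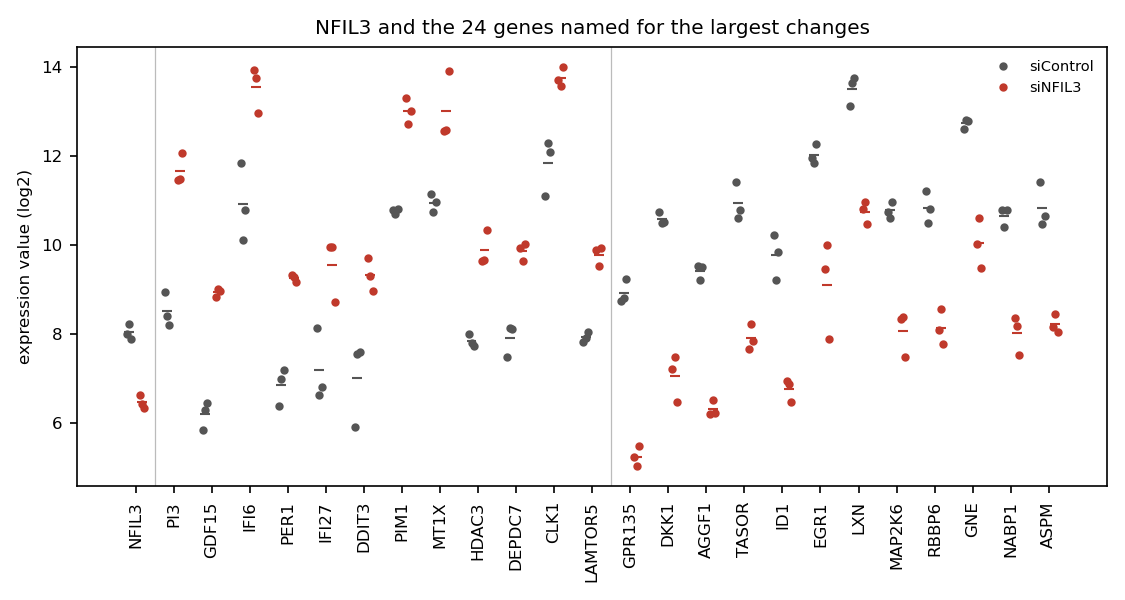
Log2 level on each array for NFIL3 and the 24 genes that the naming rule picked, siNFIL3 against siControl. That rule passed over small RNAs and pseudogenes. In each gene the 3 siNFIL3 points and the 3 siControl points do not overlap, from GPR135 with a log2 fold of -3.69 to PI3 with 3.16.

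In all, 5171 of 22445 genes (23%) changed, 2572 upward and 2599 downward. At least 1.5-fold changes were made by 2384 genes, 1121 upward and 1263 downward, and at least 2-fold changes by 803. At an unadjusted p under 0.05 there were 7400 genes. The groups did not overlap in 8803 genes, 39.2% of those tested, where chance gives 10%. With the arrays centred on their medians 42.3% of the calls were upward, against 49.7% as deposited.

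Of the 27 gene lists, 7 passed camera's threshold, all upward: hypoxia-inducible genes, glycolysis, cytosolic ribosomal proteins, nuclear oxidative phosphorylation, autophagy and lysosome, interferon response and housekeeping genes. With an estimated inter-gene correlation camera passed 0 lists, and 0 lists had an unadjusted p under 0.05, while fry passed 9. Fry tests whether a list's genes move one way on balance, without comparing them with other genes. It passed those of the 7 lists other than interferon response (adjusted p = 0.143), and also genes linked to NFIL3 before (0.0244), granulocyte and monocyte markers (0.0279) and epithelial and fibroblast markers (0.0465). Other splits of the 6 arrays into 3 and 3 gave up to 13 lists with the preset correlation. Those splits mixed arrays of both siRNAs and still carry part of their difference, so they give no rate of calls without it.

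Many hypoxia-inducible and glycolysis genes, but not all, were higher than in the hypoxic controls. The lists' calls were lost with an estimated correlation (adjusted p = 0.851 and 0.835). Of 39 measured hypoxia-inducible genes, 21 rose and 0 fell (25 and 1 adjusted over the list alone; 26 and 2 at an unadjusted p under 0.05), with a median log2 fold of 0.47. ANGPTL4, a lipoprotein lipase inhibitor, rose by 1.498 (SE 0.26) and the hexokinase HK2 by 1.46 (SE 0.16). With the preset correlation the list's camera adjusted p was 8.31e-06. Of 19 glycolysis genes, 12 rose and 1 fell (15 and 2 adjusted over the list alone), with a median of 0.38. The enolase ENO2 rose by 1.63 (SE 0.20), and HK2 belongs to this list too. The lactate dehydrogenase subunit LDHB fell by 0.28 on the log2 scale and missed the threshold without siNFIL3 replicate 1, 2 or 3 or siControl replicate 1 or 3 (adjusted p 0.0954, 0.0995, 0.113, 0.072 and 0.108). The glycolysis list also had an adjusted p of 8.31e-06 with the preset correlation.

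Of 51 cytosolic ribosomal protein genes, 33 rose and 0 fell (38 and 1 adjusted over the list alone; 39 and 1 at an unadjusted p under 0.05), with a median of 0.365. RPS27L rose by 1.08 (SE 0.08) and RPL36 by 0.92 (SE 0.13). The adjusted p was 9.18e-12, with adjusted p = 0.835 with an estimated correlation. Of 69 nuclear oxidative phosphorylation genes, 28 rose and 3 fell (31 and 4 adjusted over the list alone), with a median of 0.23. The cytochrome c oxidase subunits COX8A and COX7B rose by 1.38 (SE 0.27) and 1.27 (SE 0.105), and the complex I subunits NDUFB5 and NDUFS1 fell, with log2 folds of -0.585 (SE 0.08) and -0.51 (SE 0.07). The adjusted p was 6.66e-05, with adjusted p = 0.835 with an estimated correlation. Of 12 housekeeping genes, 4 rose and 0 fell (5 and 0 adjusted over the list alone; 6 and 0 at an unadjusted p under 0.05), among them GUSB (0.54, SE 0.11) and B2M (0.50, SE 0.10). This list's median was 0.16 and its adjusted p 0.0273, with adjusted p = 0.835 with an estimated correlation. It did not pass after quantile normalization (median 0.08, adjusted p = 0.331), among genes above the table median (0.0532) or without siControl replicate 2 (median 0.14, 0.0635).

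Of 35 autophagy and lysosome genes, 15 rose and 2 fell, both also adjusted over the list alone, with a median of 0.145. GABARAPL1 and GABARAPL2, which encode ATG8-family proteins of the autophagosome membrane, rose by 1.595 (SE 0.34) and 1.57 (SE 0.12), and the kinase ULK2 fell by 0.30 (SE 0.06) on the log2 scale. The adjusted p was 0.00619, with adjusted p = 0.851 with an estimated correlation. GABARAPL1 missed the threshold without siNFIL3 replicate 1 (1.41, adjusted p = 0.0559) or 3 (1.604, 0.0501).

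Of 34 interferon response genes, 9 rose and 1 fell, the same counts as adjusted over the list alone, and IFI6 and IFI27 rose most. The list's median was 0.15 as deposited, 0.093 after quantile normalization and 0.103 with arrays centred. IFI6 was at 13.55 ± 0.51 in siNFIL3 and 10.91 ± 0.86 in siControl. The adjusted p was 0.026, with adjusted p = 0.965 with an estimated correlation. Without siControl replicate 2 or 3 the list did not pass (median 0.11 and 0.08, adjusted p = 0.14 and 0.0882), whereas without siControl replicate 1 its median was 0.36. IFI27 missed the threshold without siControl replicate 3 (2.17, adjusted p = 0.0564) or siNFIL3 replicate 1 (2.15, 0.0525).

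**Figure D3:**
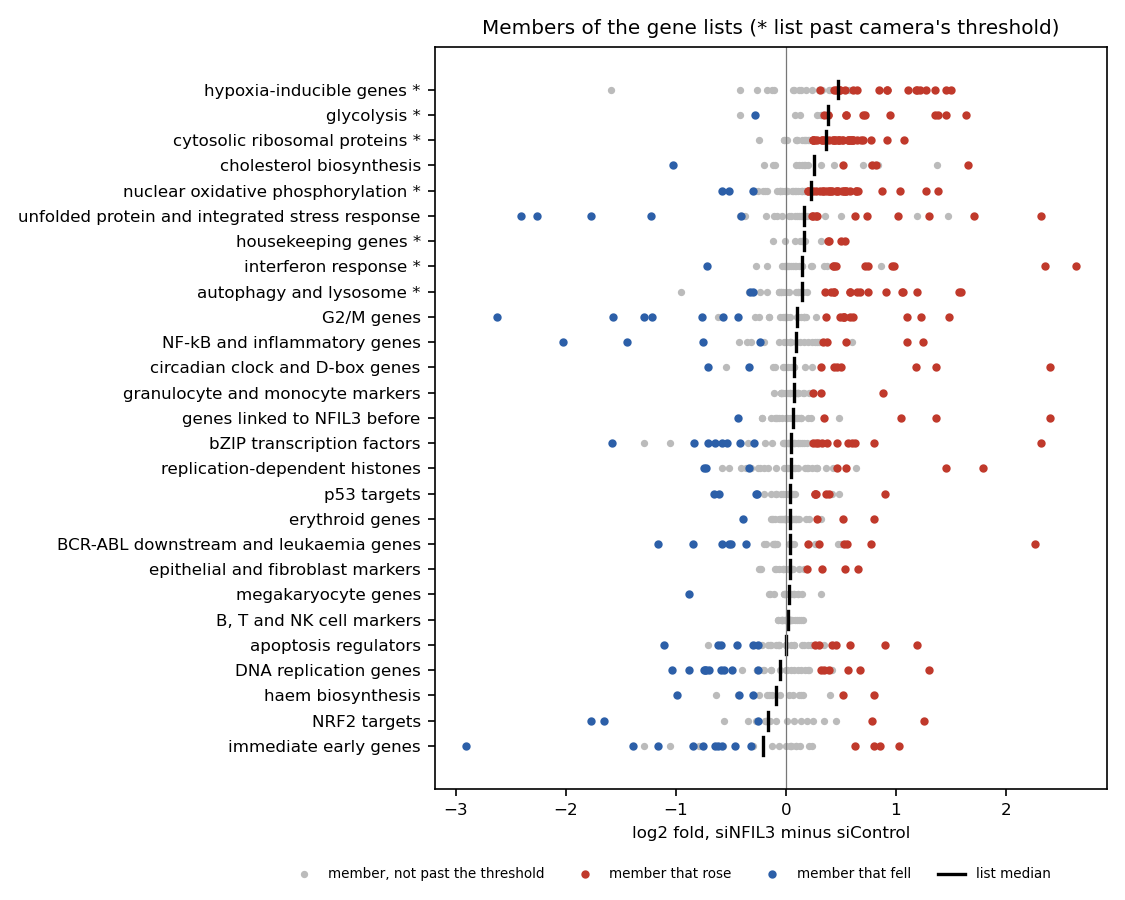
Log2 fold (siNFIL3 minus siControl) of each measured member of the 27 lists. Points are genes, with those that rose or fell coloured, and black bars are list medians of the values as deposited, from -0.21 for immediate early genes to 0.47 for hypoxia-inducible genes.

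Some clock genes that NFIL3 is known to repress, or that act beside it, changed, in both directions. Of 21 clock and D-box genes, 7 rose, 2 fell and 12 did not pass, and as many rose and fell adjusted over the list alone. PER2 (-0.097, limma adjusted p = 0.487) and PER3 (0.063, 0.674), picked after their values were seen, were among those that did not pass. PER1 rose from 6.85 ± 0.42 to 9.25 ± 0.08 (2.40, SE 0.20) and the nuclear receptor gene NR1D1 from 7.07 ± 0.60 to 8.43 ± 0.06 (1.36, SE 0.27), while CLOCK fell by 0.71 (SE 0.11) on the log2 scale. The list did not pass (adjusted p = 0.19). Of 27 genes linked to NFIL3 before, 4 rose and 1 fell, as they did adjusted over the list alone, and PER1 and NR1D1 were again the ones that rose most (camera list adjusted p = 0.471, fry 0.0244). Of 48 basic leucine zipper genes, 11 rose and 8 fell (11 and 9 adjusted over the list alone; list adjusted p = 0.848). DDIT3 was highest among those that rose, and after NFIL3 the endoplasmic reticulum factor CREB3L2 fell most (-0.835, SE 0.13).

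Stress response genes split. Of 36 unfolded protein and integrated stress response genes, 10 rose and 5 fell (13 and 6 adjusted over the list alone; list adjusted p = 0.427). DDIT3 and PPP1R15A, which act downstream in the integrated stress response, rose by 2.32 (SE 0.46) and 1.71 (SE 0.11). CTH and PSAT1, enzymes of cysteine and serine synthesis, fell, with log2 folds of -2.41 (SE 0.36) and -2.265 (SE 0.33). Of 23 NRF2 targets, 2 rose and 3 fell, as adjusted over the list alone (list adjusted p = 0.645). The ferritin light chain gene FTL rose by 1.26 (SE 0.10) and the transketolase gene TKT by 0.78 (SE 0.09), and the cystine transporter gene SLC7A11 and the export pump gene ABCC2 fell, with log2 folds of -1.77 (SE 0.33) and -1.65 (SE 0.34). Of 24 p53 targets, 6 rose and 4 fell, as adjusted over the list alone (0.848), with the death receptor gene TNFRSF10B up by 0.90 (SE 0.07) and the repair gene XPC at -0.65 (SE 0.10). Of 33 apoptosis regulators, 7 rose and 6 fell (10 and 8 adjusted over the list alone; list adjusted p = 0.918). Among these BNIP3 rose by 1.19 (SE 0.12) and CASP8 fell by 1.11 (SE 0.10).

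Immediate early genes had a list median of -0.21, the lowest of the lists as deposited and with arrays centred, while after quantile normalization NRF2 targets were lower (-0.215 against -0.203). Of 30, 10 fell and 4 rose (11 and 4 adjusted over the list alone). EGR1 fell from 12.01 ± 0.22 to 9.10 ± 1.10 and the nuclear receptor gene NR4A3 by 1.39 (SE 0.24), and the phosphatase gene DUSP5 and the mRNA decay factor ZFP36 rose by 1.03 (SE 0.15) and 0.86 (SE 0.13). The list did not pass with all 6 arrays (adjusted p = 0.0793), but did without siNFIL3 replicate 1 (0.0284), siNFIL3 replicate 2 (0.0242) or siControl replicate 2 (0.0382), all with the preset correlation. With an estimated correlation over all 6 arrays it had adjusted p = 0.965, and by fry 0.401. Of 29 NF-kB and inflammatory genes, 5 rose and 4 fell (8 and 4 adjusted over the list alone; list adjusted p = 0.427). The cytokine LIF rose by 1.25 (SE 0.11) and the inhibitor NFKBIA by 1.10 (SE 0.07), and NFKBIZ fell by 1.44 (SE 0.32) but missed the threshold without siControl replicate 3 (-1.41, adjusted p = 0.0703).

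Cell cycle genes went both ways. Of 37 G2/M genes, 10 rose and 7 fell (10 and 9 adjusted over the list alone; list adjusted p = 0.848). The ubiquitin-conjugating enzyme UBE2C and the kinase subunit CKS2 rose by 1.48 (SE 0.14) and 1.23 (SE 0.10), and ASPM and the kinetochore gene CENPF fell, with log2 folds of -2.62 (SE 0.24) and -1.57 (SE 0.16). Of 37 DNA replication genes, 6 rose and 10 fell (11 and 12 adjusted over the list alone; 0.471), with the licensing factor CDT1 up by 1.297 (SE 0.14) and the primase subunit PRIM1 at -1.03 (SE 0.10). Of 34 replication-dependent histones, 4 rose and 3 fell (5 and 4 adjusted over the list alone; 0.873), and H2BC21 rose by 1.79 (SE 0.23). Of 20 cholesterol synthesis genes, 4 rose and 1 fell (5 and 1 adjusted over the list alone). That list's adjusted p was 0.177, but 0.0148 without siNFIL3 replicate 3 and 0.0382 without siControl replicate 2, all with the preset correlation. With an estimated correlation over all 6 arrays it had adjusted p = 0.965, and by fry 0.43.

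Few blood lineage genes changed. Median levels of the erythroid, megakaryocyte and other blood cell lists ran from 3.41 to 3.58, below the table median of 3.72. Most of their members could not be told from background, so few calls could be made and they say little about these genes. The rises counted here include HBZ (2.64 to 2.92) and CAMP (3.72 to 3.97), at such levels. Of 35 erythroid genes, 3 rose and 1 fell (2 and 0 adjusted over the list alone; list adjusted p = 0.645), led by BLVRB (0.80, SE 0.10) and the mitochondrial iron importer SLC25A37 (0.52, SE 0.09). Of 18 haem synthesis genes, 2 rose and 3 fell (2 and 5 adjusted over the list alone; 0.645), the former being the same BLVRB and SLC25A37, and the transporter ABCB10 and the ferrochelatase FECH fell, with log2 folds of -0.99 (SE 0.13) and -0.43 (SE 0.08). Of 19 megakaryocyte genes, 0 rose and 1 fell (0 and 0 adjusted over the list alone; 1 and 1 at an unadjusted p under 0.05; 0.973). Of 27 granulocyte and monocyte markers, 3 rose and 0 fell, as adjusted over the list alone (5 and 0 at an unadjusted p under 0.05; 0.203), with the lysosomal CD68 up by 0.88 (SE 0.11). Of 24 B, T and NK cell markers 0 changed by limma, also adjusted over the list alone, and 1 had an unadjusted p under 0.05 (list adjusted p = 0.848). Of 20 epithelial and fibroblast markers, 4 rose and 0 fell, as adjusted over the list alone (5 and 1 at an unadjusted p under 0.05; 0.824), and KRT19 rose from 7.17 ± 0.16 to 7.83 ± 0.11. Of 28 BCR-ABL downstream and leukaemia genes, 6 rose and 6 fell (8 and 6 adjusted over the list alone; 0.918). PIM1 rose from 10.75 ± 0.06 to 13.02 ± 0.29 and PIM2 by 0.77 (SE 0.08), while the phosphatase gene DUSP6 fell, with a log2 fold of -0.845 (SE 0.17). The oncogene MYC fell by 1.16 (SE 0.31), and missed the threshold without siNFIL3 replicate 1 (-1.29, adjusted p = 0.0609), siControl replicate 1 (-0.98, 0.0793) or siControl replicate 3 (-1.17, 0.0991). Median, mean and test differed in sign for G2/M genes (median 0.105, mean -0.03), megakaryocyte genes (0.03 and -0.02), apoptosis regulators and histones (camera downward, medians 0 and 0.04). These are values as deposited. After quantile normalization the G2/M median was 0.005 and the megakaryocyte median -0.02, and with arrays centred 0.062 and -0.018.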

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

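Transcript clusters outside the comparison of named genes changed too, and were singled out because they belong to data the report does not use. With p adjusted over all 65528 rows, 3630 of the rows without a gene symbol here changed between siNFIL3 and siControl (8.8% of them), 2029 upward and 1601 downward. Of the rows with several symbols, 256 changed (18.4%), 131 upward and 125 downward. Under the same adjustment 17.4% of the rows with 1 symbol changed. No explanation was tested for these rows.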

How the results depend on the processing

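The alternative of protein-coding genes alone was chosen after seeing the data; the others were planned and all ran. NFIL3 was lower past the threshold in every alternative that tested it, with log2 folds from -1.66 to -1.49 when 1 array was left out. Leaving out an array gave 3842 to 5107 changed genes, 2073 to 2438 of at least 1.5-fold and 6 to 8 lists. With fewer arrays the test has less to work with; no gene called both with and without an array changed direction. With the replicate number as a block, 4223 genes changed, 4058 of them among the 5171. Deviations of same-numbered arrays correlated at -0.08, -0.06 and -0.19, and those of differently numbered arrays at -0.081 to 0.185. The values thus showed no pairing by number, but whether same-numbered samples shared an origin is not given by the labels. Testing all rows gave 7848 changed, 4110 upward, since more rows were tested. An adjusted p under 0.01 left 2862 (1363 upward, 1499 downward), and an unadjusted p under 0.05 with at least 1.5-fold 2491 (1178 and 1313). The unmoderated model left 2895 (1424 and 1471); the cause was not tested. With an estimated correlation 0 lists passed. Among the 7 lists that had passed, estimates ran from 0.043 for housekeeping genes to 0.391 for hypoxia-inducible genes. All were above the preset 0.01, so camera allowed for more shared variation within each list. How much this alone lowered the count was not tested. Quantile normalization gave 5237 changed genes, centring 4903 and protein-coding genes alone 4516. Of the single named genes' values, 1168 kept direction and side of the threshold and 92 kept direction only. Of the lists' values 384 kept both, 8 newly passed and 13 no longer passed. Signal near the array floor limits what can be said of dim genes.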

Other observations

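Several classes of small non-coding RNA were noticed after their values were seen, and differences between classes in the share of genes that rose were not tested. Of 239 snoRNA genes, whose RNAs guide the modification of ribosomal and spliceosomal RNA, 113 rose and 3 fell, with a median log2 fold of 0.42. SNORD59A rose from 8.81 ± 0.15 to 12.61 ± 0.42 (log2 fold 3.81, SE 0.20) and SNORD63 from 11.43 ± 0.13 to 13.80 ± 0.18 (2.38, SE 0.11). Of 23 snRNA genes, 11 rose and 0 fell, and of 4 Y RNA genes 3 rose, RNY5 by 1.57 (SE 0.15). Of 1039 miRNA genes, by contrast, 67 rose (6.4%) and 49 fell, with a median of 0.03. Among 17072 protein-coding genes 1867 rose (10.9%) and 2350 fell, with a median of 0.02. The snoRNA median was 0.36 after quantile normalization and 0.38 with arrays centred, whereas the protein-coding median was -0.01 and -0.02 and the miRNA median also turned negative in both. Of 936 pseudogenes, 319 rose and 9 fell, with a median of 0.27, whereas of 758 transcribed pseudogenes 59 rose and 70 fell. Probes for pseudogenes can also read their parent genes.

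The tests below on blood lineage genes were all chosen after the levels were seen, as were those on miRNA above a set level, on other short RNAs and on glycolysis alone. The other snoRNA tests and those of the 4 lists that rose together were set down before they ran, but for patterns already seen. For the number of genes changed, 10 splits of the 6 arrays are too few for a share under 0.05. The real split gave 5171 changed genes and 2384 of at least 1.5-fold, and the highest of the other splits 0 by limma, with up to 1001 at an unadjusted p under 0.05. In both cases 1 of the 10 splits, the real one, gave a result as large. Every other split mixed arrays of both siRNAs in each group, so the siRNA difference itself widened the spread within groups. Low counts were thus built in there and do not measure chance. For the lists, 4 of the 10 splits gave as many as the real 7, the highest other 13, and what gave those calls was not tested. The mixed splits still carry part of the siRNA difference, so they give no rate of calls without it.

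Blood lineage genes lay near the bottom of arrays labelled K562, a line known for erythroid genes such as GATA1. Rows joined to wrong names are argued against by the housekeeping list, at a median percentile of 98. RNA of a cell line other than K562 is a candidate explanation: 11.4% of the erythroid list lay above the 75th percentile, and those 4 genes are not erythroid-specific. In 2 siControl samples the source label also gave another number after the K than the cell line label did. Loss of erythroid transcripts through hypoxia or transfection cannot be told apart from this, since 0 arrays lacked either, and the high levels in siNFIL3 and siControl of KRT8 (12.45 and 12.19), KRT18 (13.31 and 13.14), EGFR (11.08 and 11.69) and MET (11.02 and 10.9), genes picked after their values were seen, have no such array to be set against either.

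The snoRNA rise was set against more small or intronic RNA and against host genes. A rise of host genes is argued against for the 85 snoRNAs with 1 measured gene around them. Their log2 folds exceeded those of their 70 hosts by a median of 0.929 (95% interval 0.664 to 1.261). Of the 85, 80 lay above their host, and the hosts' median was -0.014. These 85 had a median of 0.967, against 0.42 over all 239 snoRNA genes, and the rest were not set against hosts. The first miRNA comparison (excess over protein-coding genes 0.006) decides nothing, as most miRNA rows were dim. The miRNA excess was 0.04 above the table median (interval 0.01 to 0.07) and 0.161 at the snoRNA level (0.037 to 0.243). Both lay below 50% of the snoRNA excess (0.413 and 0.528). This argues against an equal rise of all short intronic RNA, as far as miRNA rows read it. The intervals lay above 0, so a smaller rise stays open, and miRNA rows at the snoRNA level were dimmer (median 7.73 against 8.96). Other short RNAs without host introns exceeded protein-coding genes by 0.528 (0.159 to 0.805), so a larger share of short RNA in the siNFIL3 samples may account for the rise. An effect of NFIL3 depletion on these RNAs also stays open, as RNA recovery was not measured.

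The ribosomal protein, oxidative phosphorylation, glycolysis and hypoxia lists had positive medians and passed camera with the preset correlation, but none of the 4 passed with an estimated one (adjusted p 0.835, 0.835, 0.835 and 0.851). Differences in scale left between the deposited columns did not make most of these medians, since 4 of 4 kept more than 50% of their size after quantile normalization. RMA had already quantile-normalized the probes and the columns were close to a common scale, so little change was possible. A distortion made by RMA itself could not be seen this way, so scaling as a source stays undecided. A trend with expression level is argued against for 3 of the 4 lists, at percentiles 99.91, 99.96 and 100 of level-matched random lists for ribosomal proteins, oxidative phosphorylation and hypoxia genes. The glycolysis list, at 95.87, lay within the range of its matched lists (-0.146 to 0.403), so such a trend is not excluded there. Its median of 0.38 was above the matched lists' median of 0.121. That range also holds the spread between random lists of 19 genes, so the test does not decide for glycolysis. A bias by transcript length and an off-target effect of the siRNA were not tested and stay open beside NFIL3 depletion.

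Among lists that did not pass, immediate early genes lay at percentile 0.4 and NRF2 targets at 1.69 of their level-matched random lists. Such lists take no account of correlation between members, and with an estimated correlation both had camera adjusted p = 0.965. Of the lists that passed, interferon response lay at 100, with a median of 0.146 above the matched range of -0.054 to 0.084. Its camera call was lost with an estimated correlation (adjusted p = 0.965). The autophagy and lysosome list lay at 94.94, within the range of its matched lists. The housekeeping list lay at 52.18, and its call was lost with an estimated correlation (adjusted p = 0.835) and after quantile normalization (median 0.08, adjusted p = 0.331).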
